A study of Mus musculus with 2 samples.

How the data were processed

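YY1 chromatin immunoprecipitation and sequencing (ChIP-seq) was done on pro-B cells of Rag1-deficient C57BL/6 mice. YY1 is a zinc-finger transcription factor, and pro-B cells are the B-lineage stage at which the immunoglobulin heavy chain locus (Igh) rearranges. Rag1 is part of the recombinase, so these cells keep Igh in its unrearranged form. Per the labels' protocols, bone marrow cells were enriched for CD19 with magnetic beads and crosslinked with formaldehyde, the chromatin was sonicated, and YY1 was precipitated with antibodies from 2 suppliers. The series holds 1 YY1 library and 1 library of input chromatin, the uncaptured DNA that serves as background. The labels give no replicate for either, so no spread between samples can be given and no test between conditions was made.

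Per the submitters' processing notes, Bowtie was named as a tool and mm9 as the genome build. The peak caller, its threshold, any removal of duplicate reads and the way the input was used are not given in the sources used here. The authors deposited the YY1 result as a list of chromosome, start and end positions, under a genome browser track line. All 55778 entries span 25 bp, on 1 fixed grid per chromosome, and adjacent entries share a bound. They were therefore read as 0-based half-open intervals, and positions are printed 1-based in mm9. The deposited list holds no read count, height, fold or p-value, so the depth of the YY1 library is unknown and peaks could not be ranked by strength. Whether the intervals had already been filtered against the input is not given either. No values of the input library were analysed here, so no background level is set beside a region.

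Intervals at most 500 bp apart were joined into regions, which are the unit of the counts below. The 500 bp distance was fixed before the data were examined, as an alternative to the deposited entries. It became the unit of the text after the file was seen to hold 25 bp pieces. Of the gaps between runs of adjoining intervals, 968 measured at most 200 bp and only 69 lay between there and 500 bp, so few joins depended on the exact distance. The span of a region runs from its first to its last interval, and its covered length counts only the intervals inside it. Neither is a measure of binding strength.

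No genome sequence and no mm9 annotation were used. A RefSeq gene table of a later mouse assembly was used only for gene symbols and for the number of protein-coding genes on each chromosome, since its coordinates do not apply to mm9. Single regions were therefore not assigned to genes. The shares of regions at promoters and with the YY1 motif and the promoter counts of the gene lists fixed before the data were examined (ribosomal, respiratory chain, B-lineage, recombination, Polycomb and others) were not run for this reason. The comparison of peak strength was not run because the list holds no score. The genes to be named in all cases under the rule fixed in advance, among them Yy1, Pax5, Ebf1, Ctcf and Rag1, were not analysed here. That rule also named the peaks with the highest score. With no score in the list, the 10 regions with the most intervals stand in their place, a choice made after seeing the file. The rule's other part, every peak in the Igh locus, was kept. The bounds of Igh and of the other antigen receptor loci come from general knowledge of mm9, were rounded to 100 kb, and were written down after the file was seen.

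Chromosome counts were given with exact Poisson 95% intervals and shares with Wilson 95% intervals. Both cover counting error only. The length of a chromosome was taken from its first to its last region. Relations over the 19 autosomes and X were tested by 2-sided permutation (100000 permutations, 4 relations, Benjamini-Hochberg adjustment). Chromosomes are not replicates of the experiment, and these p-values describe the pattern within 1 library. Counts in a locus were set against 10000 random windows of the same length on the same chromosome. Spacing was set against 100 uniform random placements of the same regions on their own chromosomes. On simulated data the joining step recovered 2000 of 2000 planted regions. These were all planted too far apart to be joined with one another, so crowded regions were not tested. Uniform placements gave 2.11% of neighbours within 10 kb, against 1.98% from the closed form. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The alternatives tried were other join distances, minimum numbers of intervals, wider locus bounds, other gene sets, and leaving out chromosome X, chromosome Y or the start of chromosome 9.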

Results

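YY1 occupancy in Rag1-deficient mouse pro-B cells was given as 55778 intervals of 25 bp on 21 chromosomes, which together covered 1.39 Mb of mm9. They formed 4167 regions after intervals within 500 bp were joined. The list belongs to the series' only YY1 library, so the values below describe that library and carry no replicate error. The design also names 1 input library, and how it entered the list is not known. The depth of the YY1 library is unknown, and that of the input was not analysed here.

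YY1 regions were short and mostly unbroken. The median span was 325 bp, with quartiles at 100 bp and 575 bp and a maximum of 3225 bp. In 3339 regions (80.1%) the intervals ran without a break, counting regions of a single interval, which cannot have one. At least 13 intervals were held by 2002 regions, and a single interval of 25 bp made up 406 (9.74%, 95% Wilson interval 8.88 to 10.7%). A further 301 regions spanned 50 bp and 229 spanned 75 bp, and among longer spans the counts had 2 main local maxima. A span of 325 bp occurred in 338 regions and a span of 600 bp in 204, with only 51 regions at 400 bp between them. The region with the most intervals lay on chromosome 5 at 22938596 to 22941820 and held 104 intervals over 3225 bp. By number of intervals it was followed by a region of 1775 bp on chromosome 17 at 34255702 to 34257476, with 71 intervals, and one of 1750 bp on chromosome X at 71211211 to 71212960, with 70 intervals. The remaining 7 of the 10 regions with the most intervals lay on chromosomes 1, 2, 3, 7, 11 and 15, with 55 to 66 intervals each.

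**Figure D1:**
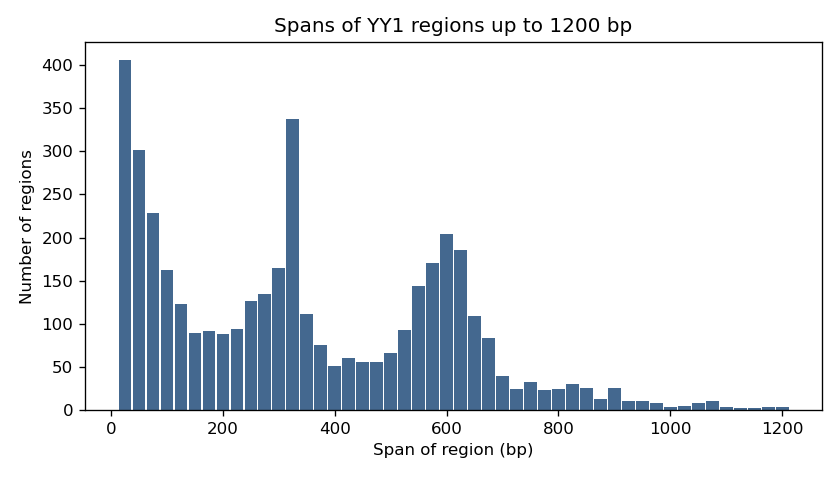
Number of YY1 regions (vertical axis) at each span in bp (horizontal axis), for regions of up to 1200 bp. Single intervals of 25 bp are the most frequent, with 406 regions, and there are further local maxima at 325 bp and 600 bp.

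The series title places the question at Igh, the heavy chain locus near the end of chromosome 12, and at its distal variable (VH) part, where PAIR elements give rise to non-coding transcripts. Within the locus 6 YY1 regions were listed. All 4 that held more than a single interval lay in the part nearer the start of the chromosome. That side of the locus holds the constant gene segments and their enhancers in mm9. The broadest covered 600 bp without a break, from 114665511 to 114666110, with 24 intervals. General knowledge of mm9 puts the intronic enhancer Eμ, which lies between the joining segments and the first constant gene and is a long-known YY1 target, at about this position. No mm9 annotation was used to check that placing. A second broad region, with 19 intervals over 550 bp, lay at 114559286 to 114559835 within the constant gene part. The region at 114405111 to 114405210 and the one at 114406261 to 114406510 held 4 intervals each. They lay close to the bound used for the locus, so their membership depends on it. They may lie outside the part with the constant gene segments and enhancers. The other 2 were single intervals on the VH side of the broadest region, at 114685811 to 114685835 and at 115097561 to 115097585.

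No YY1 region was listed in the distal VH part of Igh. From 115097586 to 117518685 chromosome 12 held none, a stretch of 2.42 Mb of which 2.20 Mb fell inside the locus bounds. The next region, at 117518686 to 117519160, lay beyond the locus. A stretch of this length without a region was not unusual in the list. Among 10000 random windows of 2.20 Mb on chromosome 12, 25.3% held no region. Of the 153 gaps between regions on chromosome 12, 12 were at least as long, and over the genome 238 of 4146 (5.74%) were. The count of 6 regions in 2.9 Mb (exact Poisson 95% interval 2.20 to 13.1) was also within the range of the chromosome, since random windows of that length had a median of 3 regions and 22.4% of them had 6 or more. The region at 114665511 ranked 25 among the 154 regions of chromosome 12 by number of intervals, and 78.8% of all regions had fewer intervals. The absence of a listed region is not a measured absence of YY1, because the threshold, the depth and the treatment of reads that match several VH segments are not known.

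**Figure D2:**
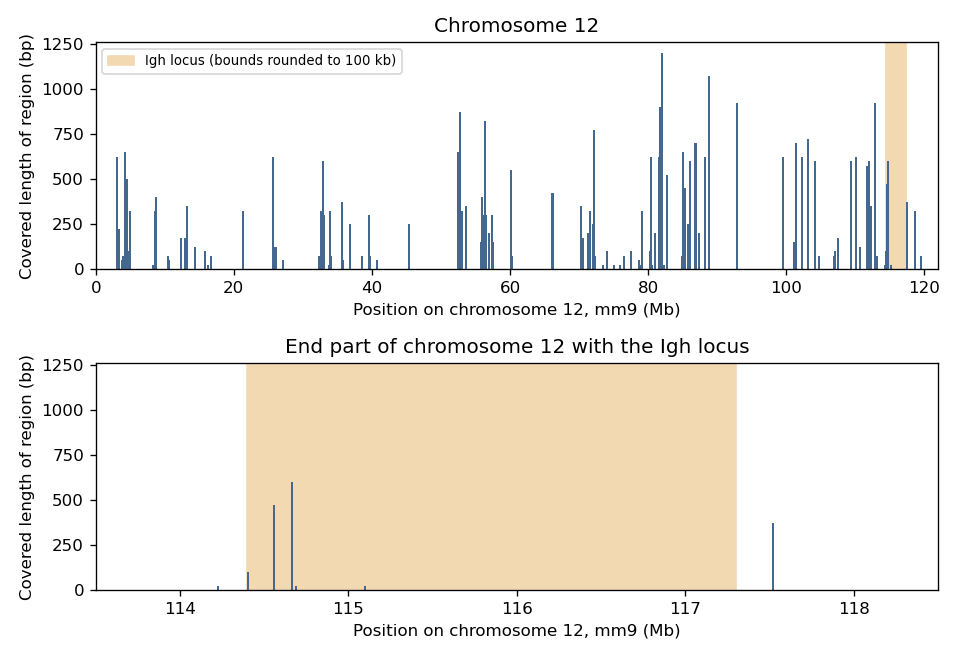
YY1 regions along chromosome 12 (top) and over its end part (bottom), each drawn as a line at its mm9 start position in Mb, with its covered length in bp as the height. The shaded part is the Igh locus, and the line near its lower end that reaches 600 bp is the region at 114665511, followed by 2 single intervals and then no region up to 117518686.

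The other antigen receptor loci held at most 2 YY1 regions each, over lengths of 0.3 to 3.2 Mb. Per Mb the short Igl locus had the most of all loci counted, at 6.67, but from only 2 regions. In the kappa light chain locus Igk, on chromosome 6, a single interval at 70681146 to 70681170 was listed, at the edge of the bounds used, and 20.6% of random windows of the same 3.2 Mb held as few as 1 region. The lambda locus Igl on chromosome 16 held 2 regions in 0.3 Mb, a run of 325 bp at 19052828 to 19053152 and one of 75 bp at 19003153 to 19003227. Random windows there held 2 or more regions in 11.9% of cases. Among the T cell receptor loci, Tcrb on chromosome 6 held 1 region of 300 bp, at 41504396 to 41504695. The joint Tcra and Tcrd locus on chromosome 14 held 1 region of 125 bp, at 54679620 to 54679744. None was listed in Tcrg on chromosome 13, and 73.0% of random windows of its length also held none. The counts in these loci were too small to set them apart from the rest of their chromosomes.

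Over the genome, the density of YY1 regions rose with that of protein-coding genes, with chromosome 7 as an exception when all these genes were counted. Chromosome 11 had 2.97 regions per Mb (95% interval 2.67 to 3.30), chromosome 19 had 2.51 (2.12 to 2.96) and chromosome 17 had 2.15 (1.86 to 2.47). Chromosome 7, the densest in genes at 13.6 per Mb, had only 1.92 (1.71 to 2.16), close to chromosome 9 with 1.94 regions and 9.93 genes per Mb. Chromosome 14 had 1.14 regions per Mb (0.956 to 1.36) and chromosome 12, which carries Igh, had 1.32 (1.12 to 1.55). The autosomes thus spread over 2.60 times per Mb. Counted per 100 protein-coding genes they ran from 14.1 on chromosome 7 to 24.3 on chromosome 18, a spread of 1.72 times. Region density followed the density of protein-coding genes over the 19 autosomes and X with Pearson r = 0.83 and Spearman rho = 0.86. Both permutation p-values were 1e-05 (adjusted 2e-05), the smallest that 100000 permutations can give. Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.84. Of the 2030 protein-coding genes of chromosome 7, 970 were predicted genes or in symbol families. A symbol family here is at least 5 protein-coding genes of the same chromosome whose symbols share their first letters. With both classes left out on every chromosome, r was 0.94. The lowest autosome was then chromosome 14, at 22.8 regions per 100 genes.

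The number of regions per chromosome rose with the number of protein-coding genes (r = 0.86, rho = 0.90, both permutation p = 1e-05, adjusted 2e-05; r = 0.86 without chromosomes 2 and 7). Its relation to spanned length was looser, with r = 0.50 (permutation p = 0.023, adjusted 0.023) and rho = 0.55 (p = 0.013, adjusted 0.014), and without chromosomes 1 and 19 r was 0.45 (p = 0.058) and rho 0.48 (p = 0.045). The difference between these correlations was not tested. The number of chemoreceptor genes, the large olfactory and vomeronasal receptor families that pro-B cells are not known to use, gave r = 0.56 (permutation p = 0.010, adjusted 0.013) and rho = 0.55 (p = 0.014, adjusted 0.014). Without chromosomes 2 and 7 r was 0.38 (permutation p = 0.12) and rho 0.40 (p = 0.097), so the relation no longer passed the test. Chromosome 7 carries 418 of the 1482 chemoreceptor genes. It had the fewest regions per 100 genes among the autosomes when all protein-coding genes were counted, but not without symbol families and predicted genes.

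**Figure D3:**
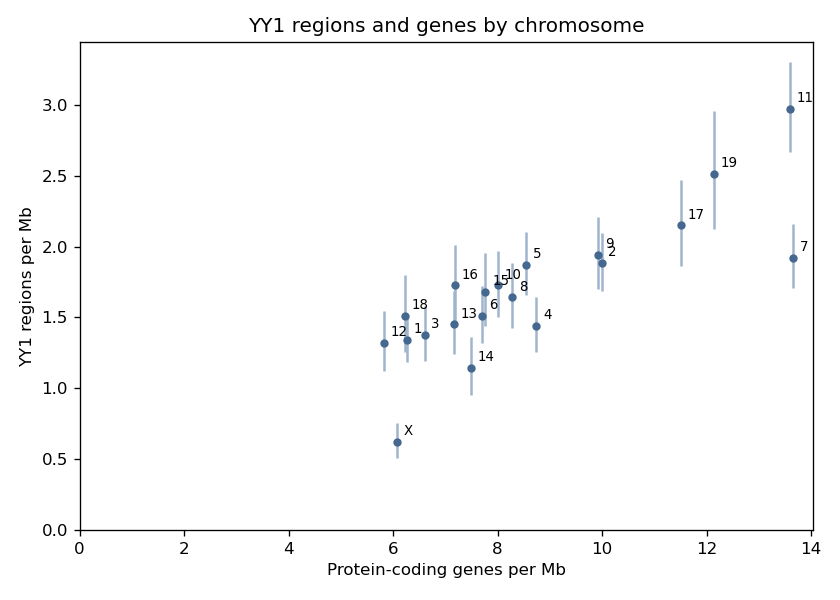
YY1 regions per Mb (vertical axis) against protein-coding genes per Mb (horizontal axis) for the 19 autosomes and X, each point labelled with its chromosome, with exact Poisson 95% intervals as bars. Chromosome 11 is highest at 2.97 regions per Mb and chromosome X lowest at 0.621.

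Chromosome X had 99 regions, or 0.621 per Mb (95% interval 0.505 to 0.757) and 10.2 per 100 protein-coding genes (8.33 to 12.5). The autosomes together had 4064 regions, or 19.7 per 100 genes, and the lowest of them, chromosome 7, had 14.1 (12.5 to 15.8). X therefore had 0.521 times the autosomal number per gene (0.424 to 0.634, from the counting error of the X regions). The longest stretch without a region was also on X, from 110299236 to 131120260, or 20.8 Mb. Chromosome Y had 4 regions, of 325 to 800 bp, all between 346727 and 2766101.

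YY1 regions lay closer together than uniform random placement gave. Of 4146 pairs of neighbouring regions, 244 (5.89%, 95% Wilson interval 5.21 to 6.64%) were at most 10 kb apart. The 100 random placements on the same chromosomes gave a mean of 1.70% with an SD of 0.190, and their highest value was 2.12%. Their starts were drawn uniformly between the first and last region of each chromosome, without regard to genes. They therefore cannot show whether regions lay closer than their relation to gene density alone would give. How many of the close pairs are pieces of 1 site was not examined. In windows of 100 kb, 2707 held 1 region, 484 held 2, 115 held 3, 18 held 4 and 12 held 5. A single window held more, the one at the start of the assembled part of chromosome 9, with 15 regions between 3000026 and 3036550.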

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

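The number of deposited entries, 55778, depends wholly on how pieces are counted, since merging entries within 500 bp left 4167, while leaving out chromosome Y left 55686. The number of regions stayed within 1.5 times of 4167 in 8 of 9 settings, all chosen after seeing the data, from 5204 when only adjoining intervals were joined to 4010 at 5 kb and 3167 with at least 4 intervals. Requiring at least 13 intervals left 2002. In the Igh locus the 53 deposited entries became 6 after merging and 54 with bounds extended by 200 kb. Over 7 settings added later the locus held 4 to 8 regions, and 4 remained when single intervals were left out. The correlation of region density with gene density lay between 0.67, for single-interval regions, and 0.94, for genes without symbol families and predicted genes. The permutation p was at most 0.00091 in all 8 added settings. The share of neighbours within 10 kb was 4.43% after joining at 1 kb and 4.77% with at least 4 intervals. No random placements were made for these 2 settings. Alternatives fixed in advance that needed a score or fold, a TSS annotation, gene lists or the genome sequence were not run. No paired analysis was possible because each group has 1 library. What depth limits could not be measured, since the list holds no counts.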

Other observations

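The immunoglobulin loci differ in how many gene segments the gene table names on their chromosomes. Chromosome 12 has 183 named Ighv symbols, 20 Ighd and 4 Ighj, and the Igh locus had 6 regions. Chromosome 6 has 162 named Igkv symbols, and Igk had 1 region of a single interval. Chromosome 16 has 3 named Iglv symbols, and Igl had 2 regions. With counts this small, and overlapping Poisson intervals, no relation between segments and regions was tested.

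The tests of the crowding on chromosome 9, of the read extension and of the X region spans were chosen only after the result was seen. Regions crowded at the start of chromosome 9, with 15 of them in 36.5 kb. No autosome and no X chromosome had an interval in its first 3 Mb, and this group began at 3000026, the lowest position listed on any of those 20 chromosomes. Intervals filled a mean of 71.5% of its 13 regions of at least 250 bp, against 94.3% (SD 3.73) in 10000 draws of span-matched regions, none of which was as low, but the join distance itself can lower this share where regions lie close together. Joined at 200 bp, 0.49% of draws were as low, at 100 bp 12.96% and at 50 bp 6.8%. A shorter join also breaks a ragged region into pieces, which raises the filled share by itself. Over these joins the 15 regions became 19, 24 and 27, and those of at least 250 bp numbered 14, 11 and 10. By the filled share, ordinary crowding of YY1 sites and ragged enrichment over repeated sequence at the assembled edge of the chromosome therefore cannot be told apart. The crowding itself was far from ordinary in this list, since no other window of 100 kb held more than 5 regions. The filled share depends on the join distance in both directions, and the sequence was not examined. No biological explanation was tested because the design gives none.

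The 2 main local maxima of span at 325 bp and 600 bp may mark different kinds of region or a step of the peak calling. If the narrower class were scattered without regard to genes, its density would not follow gene density, but the 1001 regions of 250 to 400 bp gave r = 0.75 (permutation p = 0.00018) and rho = 0.71 (p = 0.00056), and r = 0.70 without the 2 chromosomes farthest from the median. The 1095 regions of 500 to 700 bp gave r = 0.84 (permutation p = 1e-05, the smallest that can be given) and rho = 0.88, and r = 0.92 without those 2. Single-interval regions gave r = 0.67 (permutation p = 0.00091), so the relation is not particular to the narrower class. It cannot decide between different kinds of region and a step of the peak calling, since either could follow gene density. A fixed read extension seen on one strand or on both remains open, since the second span was 1.85 times the first and the list holds no strands or reads. No biological explanation was tested.

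Chromosome X had few regions per gene. Leaving out symbol families and predicted genes cannot settle whether multi-copy gene families raise the X gene count enough to account for it. That filter goes by symbols alone and does not isolate multi-copy families. With it X had 18.0 regions per 100 genes (95% interval 14.6 to 21.9). The autosomes together rose from 19.7 to 29.0. The lowest autosome, here chromosome 14, had 22.8, for which no interval was computed. The ratio of X to the autosomes rose from 0.521 to 0.620, and without chemoreceptor families alone it was 0.487. Weaker enrichment, as a lower copy number would give, was taken to predict narrower X regions. The median span of X regions differed from that of random autosomal draws by 0 bp (SD of the draws 27.9). This met the outcome written down against that explanation, an X median at or above that of the draws. Weaker enrichment could still not be told apart, because span is not a measure of strength and the list holds no heights. On X 56.6% of regions (95% Wilson interval 46.7 to 65.9%) held at least 13 intervals, against 47.8% on the autosomes. A lower number of YY1 sites per X gene in pro-B cells stays open as well, as an untested hypothesis.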
